A study of Mus musculus with 30 samples.

How the data were processed

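Bone marrow haematopoietic stem cells (HSCs) of mice were profiled by RNA sequencing in 30 libraries. Per the labels' protocols, sorted cells were lysed, cDNA was made by Smart-seq2, libraries were prepared by tagmentation, and reads of 1 end were sequenced. Smart-seq2 copies whole transcripts from poly(A) tails and does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart. The surface markers used for the sort are not given in the sources used here.

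The deposited values are normalized counts per gene, a signal scale made by the authors, in which gene counts were divided by factors that differ between libraries. Per the submitters' processing notes, the tools were FastQC 0.11.9, cutadapt 2.10, Salmon 1.2.0.0 and DESeq2 1.26.0, with the mouse build GRCm38 (mm10). How transcript estimates were summed to genes is not given in the sources used here. Normalized counts are neither whole numbers nor raw counts, so no count model was used. In each library, 9.70% to 18.5% of the low values (below 20 reads) lay on whole multiples of the value of 1 read within a tolerance of 0.001, so whole reads could not be recovered. The step of 1 read gave an estimated depth of 15.6 to 56.3 M reads per library (mean 29.9 M). Library sums of normalized counts were 27.5 to 30.7 M, and 17030 to 19417 genes had a value above 0. The most abundant gene of a library took at most 1.99% of its sum.

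The table held 35727 genes as Ensembl identifiers, of which 35422 matched a symbol and 10384 were at 0 in all libraries. Positions and gene types were taken from GENCODE M21 on GRCm38. Of the genes tested, 15289 were protein coding. Near-identical genes (Hspa1a and Hspa1b, the Hist1 histones, the Mettl7a, Tuba1 and Skint families, and the H2 genes) can share reads, and their single values are uncertain.

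Samples were grouped by the title label into 8 groups. Wild-type (WT) libraries numbered 4 at 2 months, 5 at 1 year and 4 at 2 years. Libraries labelled IL1R1 KO numbered 3, 4 and 5 at these ages, and germ-free libraries 3 at 2 months and 2 at 1 year. For 1 library, IL1R1 KO 1 year replicate 1, the title and source labels gave 1 year and the age label gave 2 months. It was kept with the 1-year group, and the other placement was run as an alternative. No label says that replicates came from separate animals, so p-values measure only the spread between these samples, part of which may be technical. No pair of libraries had identical values. The highest pairwise correlation over the tested genes was 0.968, across genes, which are not independent replicates.

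Tests were run in R 4.3.3 with limma 3.58.1, and tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Values entered as log2(normalized count + 1), so fold changes of low genes are understated. Genes with a value of at least 10 in at least 3 libraries were kept (16958 genes). A linear model with a mean per group was fitted to all 30 libraries, with an empirical Bayes trend and robust settings. Tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p of 0.05 over all tested genes in a comparison. The 13 comparisons were the ages within each genotype or housing group, IL1R1 KO or germ-free against WT at each shared age, and the differences of the age changes from those of WT.

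The gene lists were the HSC ageing signature, megakaryocyte and platelet, lymphoid priming, myeloid priming, NF-kB targets, immediate early genes, type I interferon response, interferon gamma response and antigen presentation, IL-1 signalling, cell cycle, HSC identity and quiescence, oxidative phosphorylation, cytosolic ribosomal proteins, heat shock and unfolded protein response, p53 and senescence, mitochondrial genome transcripts, and sex-linked transcripts. Markers of B and plasma cells, T and NK cells, neutrophils, monocytes and macrophages, erythroid cells, mast cells with basophils and eosinophils, and endothelial and stromal cells completed the 24 lists. The HSC ageing signature was compiled from general knowledge of aged mouse HSCs, not from these values. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over 312 list tests, and again with an estimated correlation. Members were also counted with p-values adjusted over the list alone.

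Named genes followed a rule. Il1r1 came first. For each comparison these were the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap library by library and whose mean was at least 50 in a group. For the differences of age changes, overlap was not required. Unnamed genes, pseudogenes and receptor segments were left out, and a few genes taken by the rule are not reported here. Up to 4 called members per list with the smallest p, and 11 genes fixed for all comparisons, were added. Samples, groups, tests, lists, named-gene rule and most other settings were fixed before the data were examined.

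Ageing genes shared by WT and libraries labelled IL1R1 KO were those called for the mean of both age changes, and the difference of the changes was turned along that mean. The overlap of comparisons that share WT libraries was set beside 100 simulations of unchanged groups against the same WT libraries, beside the number expected of independent lists, and beside splits of the WT libraries. The settings fixed at that point were a pseudocount of 5, no filter, a filter on a mean of at least 50, quantile normalization, a replicate block, array quality weights, the other placement of the library with disagreeing age labels, only the groups compared, and each replicate left out in turn. After the values were seen, a fit without the 6 libraries of 2 months with an Mpo value of at least 20000 was added. It leaves WT replicates 1 and 3, IL1R1 KO replicate 2 alone and germ-free replicate 2 alone at 2 months, and a lone library was assumed to vary like the other groups. Also added were 4 fits with the mean of the myeloid priming, B cell, immediate early or erythroid list as a covariate. Up to 100 other splits of the libraries were drawn per comparison.

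The functions were tested on simulated data with 200 changed genes among 16958. For WT at 2 years against 2 months, 46% of genes changed by 1 and 72% of genes changed by 2 on the log2 scale were recovered, with 9 false calls. At a mean of 100 or more these shares were 65.2% and 93.9%. For the difference of age changes at 2 years, 36% and 63% were recovered, with 7 false calls.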

Results

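HSCs, the cells that renew blood, were sequenced from WT mice, from mice labelled IL1R1 KO and from mice with a germ-free bowel. WT and IL1R1 KO groups were sampled at 2 months, 1 year and 2 years, and germ-free groups at 2 months and 1 year. Groups held 2 to 5 libraries. Estimated depth was 20.0 to 29.5 M reads in WT at 2 months, 32.6 to 56.3 M in WT at 1 year and 23.6 to 29.6 M in WT at 2 years. It was 28.6 to 35.7, 21.0 to 32.9 and 19.3 to 35.3 M in the 3 IL1R1 KO groups by age. In germ-free libraries it was 24.9 to 32.1 M at 2 months and 15.6 to 23.9 M at 1 year. By the series title, the comparisons address the part of interleukin-1 signalling and of the microbiome in the ageing of HSCs.

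Il1r1, the gene of the type 1 interleukin-1 receptor (ENSMUSG00000026072, chromosome 1, 40225080 to 40317257, GRCm38), was measured in all 8 groups. Its normalized count was 179 ± 54.8 (SD, n = 4) in WT at 2 months, 232 ± 46.2 (SD, n = 5) at 1 year and 276 ± 88.2 (SD, n = 4) at 2 years. In libraries labelled IL1R1 KO it was 231 ± 40.2 (SD, n = 3), 284 ± 80.0 (SD, n = 4) and 322 ± 67.7 (SD, n = 5) at the same ages. Germ-free libraries held 202 ± 84.2 (SD, n = 3) at 2 months and 299 ± 3.99 (SD, n = 2) at 1 year. The level was not lower in libraries labelled IL1R1 KO, with limma log2 differences from WT of 0.40 ± 0.30 (SE, adjusted p = 0.714), 0.28 ± 0.26 (SE, adjusted p = 0.751) and 0.25 ± 0.26 (SE, adjusted p = 0.804). The allele is not given in the sources used here, and a sum over the whole gene does not show a deletion of part of it. Every direction given for these libraries rests on their label.

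In WT at 1 year against 2 months, genes known to rise in aged HSCs rose together. Selp (P-selectin, an adhesion molecule of platelets and endothelium) went from 2314 ± 642 (SD, n = 4) to 15176 ± 2226 (SD, n = 5) normalized counts, a log2 change of 2.74 ± 0.16 (SE, limma adjusted p = 9.99e-13). Nupr1, a stress-induced nuclear protein, rose by 2.41 ± 0.17 (SE, adjusted p = 7.67e-11), Clu, the extracellular chaperone clusterin, by 2.04 ± 0.21 (SE, adjusted p = 7.81e-08), and Aldh1a1, a retinaldehyde dehydrogenase, by 1.61 ± 0.15 (SE, adjusted p = 1.36e-08). All 28 members of the HSC ageing signature rose, also when adjusted over the list alone. Their median was 1.69, with adjusted p = 2.17e-06 with an estimated correlation. Among the largest rises were Rassf10 (6.63 ± 0.67, SE), Mab21l2 (6.51 ± 0.84, SE), the neurotrophin Ntf3 (6.03 ± 0.79, SE) and the potassium channel subunit Kcnb2 (5.77 ± 0.58, SE). Cell cycle genes fell in 18 of 36 members (33 adjusted over the list alone; adjusted p = 0.280 with an estimated correlation). Mki67, a marker of dividing cells, fell by 1.01 ± 0.15 (SE) on the log2 scale. Interferon gamma response genes rose in 13 of 25 members (14 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation). H2-Eb1 and Cd74, both of class II antigen presentation, rose by 1.60 ± 0.30 and 1.25 ± 0.25 (SE). Oxidative phosphorylation genes fell in 19 of 50 members (34 down and 1 up adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), among them Ndufa5 at -0.59 ± 0.12 (SE).

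Markers of other blood cells moved in the same comparison. The neutrophil list had a mean log2 level of 8.56 ± 1.45 (SD, n = 4) in WT at 2 months and 4.03 ± 1.70 (SD, n = 5) at 1 year. At 2 years it stood at 7.19 ± 2.71 (SD, n = 4; 3.98 to 10.6), with 0 of 13 members called by limma against 2 months, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (adjusted p = 0.725 with an estimated correlation). At 1 year, 7 of the 13 fell (10 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation), such as Mmp8, a collagenase of neutrophil granules, at -6.87 ± 1.58 (SE) and Ly6g, a surface marker of neutrophils, at -6.20 ± 1.22 (SE). Mpo, the myeloperoxidase of granulocyte precursors, was 392, 73276, 1159 and 60867 in the 4 WT libraries of 2 months and 20.5 to 2045 in the 5 of 1 year. Of the erythroid list, 4 of 13 members fell and 1 rose (the same numbers adjusted over the list alone; adjusted p = 0.446 with an estimated correlation), Car1, a carbonic anhydrase of erythroid precursors, at -3.22 ± 0.56 (SE). Monocyte and macrophage markers fell in 3 of 13 members (7 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Mast cell, basophil and eosinophil markers fell in 2 of 7 (3 adjusted over the list alone; adjusted p = 0.596 with an estimated correlation), with a list mean of -3.09, or -2.004 without WT 2 months replicate 2 and 0.62 with the myeloid covariate. In all, 1818 genes passed, 1037 higher and 781 lower at 1 year. The count was 988 without the 6 libraries of 2 months with high Mpo (705 higher and 283 lower), 982 with the myeloid covariate and 868 with the erythroid covariate.

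In WT at 2 years against 2 months, 27 of 28 members of the HSC ageing signature rose (28 adjusted over the list alone), with a median of 1.72 and adjusted p = 2.17e-06 with an estimated correlation. Selp was higher by 2.77 ± 0.17 (SE, limma adjusted p = 1.90e-12) and Nupr1 by 2.59 ± 0.18 (SE, adjusted p = 6.93e-11). Mab21l2 rose by 7.08 ± 0.88 (SE), Rassf10 by 6.51 ± 0.70 (SE), and C4b, a complement component, by 5.75 ± 0.85 (SE). Falls included Rasl11b (-4.60 ± 0.93, SE), Svep1 (-4.29 ± 0.93, SE) and Lin28b, an RNA-binding protein of fetal blood cells (-3.61 ± 0.92, SE), whose call ended without WT 2 months replicate 4 (adjusted p = 0.0623) or WT 2 years replicate 3 (adjusted p = 0.0772). Interferon gamma response genes rose in 14 of 25 members (16 adjusted over the list alone; adjusted p = 0.0611 with an estimated correlation), including the guanylate-binding protein Gbp2 at 0.70 ± 0.11 (SE). Type I interferon response genes rose in 4 of 26 members (11 up and 1 down adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). Cell cycle genes fell in 7 of 36 members (17 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). B and plasma cell markers stood at a mean log2 level of 7.32 ± 0.788 (SD, n = 4) against 5.58 ± 1.04 (SD, n = 4) at 2 months. By limma 0 of 15 members were called, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (adjusted p = 0.608 with an estimated correlation). In all, 941 genes passed, 664 higher and 277 lower. With only the 2 groups compared, the count was 342.

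**Figure D1:**
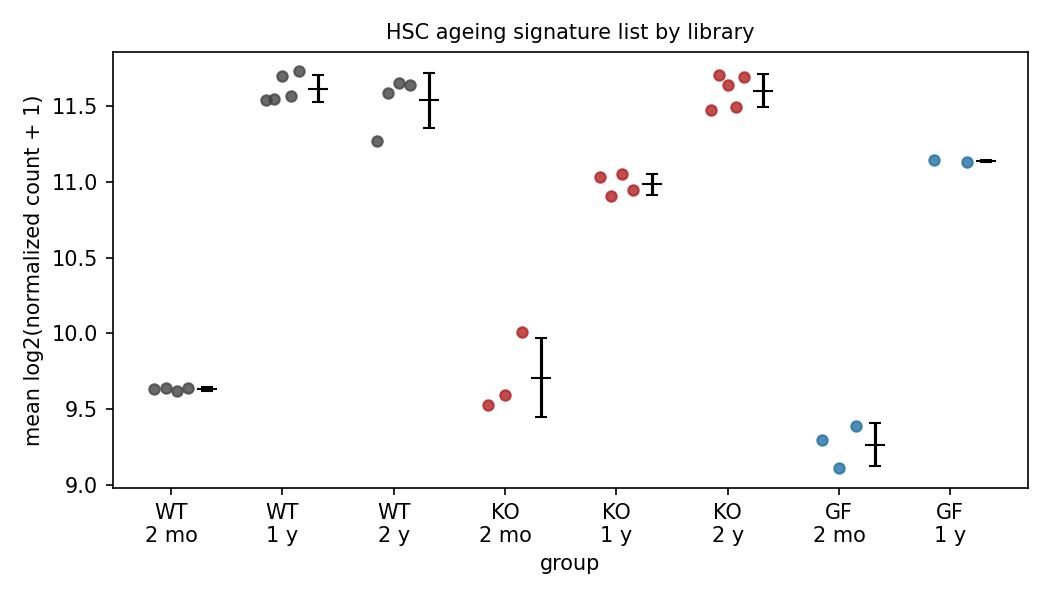
Mean log2(normalized count + 1) over the 28 genes of the HSC ageing signature (vertical axis) in each library (points) by group (horizontal axis), with the group mean and SD as a bar with whiskers. The libraries labelled IL1R1 KO average 11.0 at 1 year and 11.6 at 2 years, and WT libraries 11.6 and 11.5.

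In libraries labelled IL1R1 KO, the same list rose with age. At 1 year against 2 months, 24 of 28 members rose (27 adjusted over the list alone), with a median of 1.13 and adjusted p = 7.19e-06 with an estimated correlation. At 2 years, 27 rose (28 adjusted over the list alone), with a median of 1.80 and adjusted p = 2.23e-06 with an estimated correlation. Selp was higher by 2.40 ± 0.18 (SE, limma adjusted p = 1.53e-09) at 1 year and by 3.18 ± 0.17 (SE, adjusted p = 3.59e-13) at 2 years. Kcnb2 rose by 5.01 ± 0.66 and 6.99 ± 0.63 (SE) at the 2 ages, and Lin28b fell by 5.16 ± 1.00 and 5.78 ± 0.95 (SE) on the log2 scale. Tnc, the matrix protein tenascin C, stood at -5.89 ± 1.13 (SE) at 1 year and -5.89 ± 1.08 (SE) at 2 years. Cell cycle genes fell in 9 of 36 members at 1 year (34 adjusted over the list alone; adjusted p = 0.164 with an estimated correlation) and in 17 at 2 years (30 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation).

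Markers of other cells were measured in the same libraries. Neutrophil markers stood at 7.52 ± 1.26 (SD, n = 3) at 2 months and 5.16 ± 2.09 (SD, n = 4) at 1 year. Limma called 0 of their 13 members, also adjusted over the list alone, with 2 at an unadjusted p under 0.05 (adjusted p = 0.600 with an estimated correlation). At 2 years they stood at 8.15 ± 0.734 (SD, n = 5), with 0 of 13 called against 2 months by limma, also adjusted over the list alone, and 0 at an unadjusted p under 0.05 (adjusted p = 0.955 with an estimated correlation). Monocyte markers stood at 6.27 ± 1.46 (SD, n = 3) and 4.89 ± 0.660 (SD, n = 4), with 0 of 13 called by limma, also adjusted over the list alone, and 0 at an unadjusted p under 0.05 (adjusted p = 0.604 with an estimated correlation). Their mean difference of -1.39 was -2.11 without IL1R1 KO 2 months replicate 2 and -0.65 without replicate 3. The erythroid difference at 1 year of -0.80 was -1.59 and -0.11 in the same fits and 0.78 without the 6 high-Mpo libraries, with IL1R1 KO 2 months replicate 2 alone. Of the 13 erythroid markers 0 were called by limma, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 (adjusted p = 0.502 with an estimated correlation). Mast cell markers stood at 6.26 ± 2.54 (SD, n = 3) at 2 months and 2.29 ± 0.777 (SD, n = 5) at 2 years. Of 7 members limma called 0, with 1 adjusted over the list alone and 4 at an unadjusted p under 0.05 (adjusted p = 0.502 with an estimated correlation).

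At 2 years, transcripts of the mitochondrial genome fell in 12 of 13 members in libraries labelled IL1R1 KO (13 adjusted over the list alone; adjusted p = 0.279 with an estimated correlation), mt-Nd1 by 1.42 ± 0.24 (SE). The list mean of -0.99 was -0.62 without IL1R1 KO 2 months replicate 3. Immediate early genes, which respond within minutes to signals and to cell handling, rose in 8 of 22 members (13 up and 1 down adjusted over the list alone; adjusted p = 0.498 with an estimated correlation), Egr3 by 4.83 ± 1.02 and Nr4a2 by 2.68 ± 0.55 (SE). Heat shock genes fell in 7 of 20 members and rose in 3 (8 and 5 adjusted over the list alone), Hspa1a, an inducible Hsp70 chaperone that can share reads with Hspa1b, standing at -7.21 ± 0.91 (SE). That list did not pass (camera adjusted p = 0.0565). Counts were 340 genes at 1 year, 236 higher and 104 lower, and 1360 at 2 years, 869 higher and 491 lower. Without IL1R1 KO 2 months replicate 1 they were 94 (80 higher and 14 lower) and 753, and without IL1R1 KO 1 year replicate 2 or 3 the first was 201 or 188. With the library of disagreeing age labels placed at 2 months they were 58 and 710, the 58 being 19 higher and 39 lower, and with the immediate early covariate 166 and 709. Without the 6 high-Mpo libraries, against IL1R1 KO 2 months replicate 2 alone, they were 162 (157 higher and 5 lower) and 461 (398 and 63). With only the groups compared, the 1-year count was 50 (45 higher and 5 lower).

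In germ-free libraries at 1 year against 2 months, 26 of 28 members of the HSC ageing signature rose (28 adjusted over the list alone), with a median of 1.55 and adjusted p = 2.17e-06 with an estimated correlation. Selp rose by 2.93 ± 0.21 (SE, limma adjusted p = 4.32e-10), Nupr1 by 2.44 ± 0.24 (SE, adjusted p = 1.22e-07) and Vwf, the von Willebrand factor, by 1.36 ± 0.20 (SE, adjusted p = 1.31e-04). Rbpjl, a DNA-binding factor related to the Notch effector Rbpj, rose by 7.91 ± 0.69 (SE). Osmr, the oncostatin M receptor, rose by 5.28 ± 0.72 (SE), and Kdr, a VEGF receptor, by 2.48 ± 0.36 (SE). Falls included Disc1 (-3.26 ± 0.48, SE). Megakaryocyte and platelet genes rose in 5 of 18 members (8 adjusted over the list alone; adjusted p = 0.0546 with an estimated correlation). The neutrophil list averaged 8.86 ± 3.22 (SD, n = 3) at 2 months and 7.01 ± 0.412 (SD, n = 2) at 1 year. Of its 13 members 0 were called by limma, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 (adjusted p = 0.707 with an estimated correlation). Its mean difference of -1.85 was -3.47 without germ-free 2 months replicate 2, -0.25 without replicate 3, and 1.38 without the 6 high-Mpo libraries, with germ-free 2 months replicate 2 alone. Monocyte markers stood at 8.13 ± 2.17 (SD, n = 3) and 6.06 ± 0.0438 (SD, n = 2), with 0 of 13 called by limma, 1 lower adjusted over the list alone and 3 at an unadjusted p under 0.05 (adjusted p = 0.446 with an estimated correlation). The monocyte mean of -2.07 was -1.35 and -3.32 without germ-free 2 months replicates 1 and 2, and 0.43 in that fit with 1 library. Mast cell markers stood at 7.61 ± 4.98 (SD, n = 3) and 3.70 ± 1.18 (SD, n = 2), with 0 of 7 called by limma, also adjusted over the list alone, and 0 at an unadjusted p under 0.05 (adjusted p = 0.574 with an estimated correlation). The mast cell mean of -3.91 was -2.18, -6.77 and 1.80 in the same 3 fits. Lymphoid priming had a mean of -1.22, or -1.99 and -0.78 without germ-free 2 months replicates 2 and 3 and 0.32 with replicate 2 alone, with 1 of 18 higher and 1 lower (1 and 3 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). Myeloid priming had one of -1.19, with 1 of 18 lower (3 lower and 1 higher adjusted over the list alone; adjusted p = 0.620 with an estimated correlation). It was -0.37, -2.65 and -0.55 without germ-free 2 months replicates 1 to 3, and 1.74 with replicate 2 alone. Heat shock genes fell in 1 of 20 members (4 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), and cell cycle genes in 3 of 36 (9 adjusted over the list alone; adjusted p = 0.500 with an estimated correlation). The cell cycle mean of -0.40 was -0.19 and -0.61 without germ-free 1 year replicates 1 and 2. In all, 356 genes passed, 218 higher and 138 lower. The 1-year group had 2 libraries. The count was 193 without germ-free 1 year replicate 1, 224 without germ-free 2 months replicate 3, 133 with array quality weights (108 higher and 25 lower) and 10 with only the groups compared.

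At 2 months, libraries labelled IL1R1 KO differed from WT most in a few genes. Mettl7a2, a methyltransferase-like gene (chromosome 15, 100353200 to 100361840), was higher by 6.32 ± 0.50 (SE, limma adjusted p = 6.76e-09), and Slc5a9, a sugar transporter, by 4.48 ± 0.70 (SE, adjusted p = 5.39e-04). Skint3 (chromosome 4, 112232245 to 112300468) was lower by -7.58 ± 0.64 (SE, adjusted p = 1.34e-08), and Smarcd1, a subunit of the SWI/SNF chromatin remodeller (chromosome 15, 99702129 to 99713991), by -1.56 ± 0.17 (SE, adjusted p = 9.31e-07). These 4 genes kept their sign at the later ages, and 27 genes were called at all 3 ages with 1 sign, 15 higher and 12 lower. Of the 27, 20 started within 5 Mb of another one. The erythroid list averaged 10.1 (8.56 to 11.5, n = 3) against 9.08 ± 0.763 (SD, n = 4), with 1 of 13 members called (2 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). Its mean difference of 1.07 was 0.38 without IL1R1 KO 2 months replicate 3 and 1.86 without replicate 2. Endothelial and stromal markers stood at 7.06 ± 0.794 (SD, n = 3) against 5.68 ± 0.393 (SD, n = 4), with 0 of 9 called by limma, also adjusted over the list alone, and 2 at an unadjusted p under 0.05 (adjusted p = 0.171 with an estimated correlation). Mitochondrial genome transcripts stood at 15.3 ± 0.668 (SD, n = 3) against 14.8 ± 0.346 (SD, n = 4), with 0 of 13 called by limma, 5 adjusted over the list alone and 7 at an unadjusted p under 0.05 (adjusted p = 0.455 with an estimated correlation). Their mean difference of 0.48 was 0.11 without IL1R1 KO 2 months replicate 3 and 0.76 without replicate 2. Of 13 monocyte markers 1 was called, lower (2 adjusted over the list alone; adjusted p = 0.614 with an estimated correlation). Their mean difference of -1.01 was -1.53, -0.47 and -0.64 without WT 2 months replicates 1, 2 and 4, and -0.28 and -1.74 without IL1R1 KO 2 months replicates 2 and 3. NF-kB targets had a mean difference of -0.42, or -0.24 without WT 2 months replicate 3, with 1 of 22 members called, Rel (-0.91 ± 0.21, SE), an NF-kB subunit (1 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). The call of Rel ended in 6 of the 7 fits with 1 library left out. Heat shock genes had a mean difference of 0.36, a list call that ended without IL1R1 KO 2 months replicate 3 (0.25), with 2 of 20 members higher (7 higher and 1 lower adjusted over the list alone; adjusted p = 0.586 with an estimated correlation). In all, 69 genes passed, 41 higher and 28 lower. The count was 39 without IL1R1 KO 2 months replicate 3, 40 with array quality weights and 19 with only the groups compared (9 higher and 10 lower). It was 48 without the 6 high-Mpo libraries, 14 higher and 34 lower, with IL1R1 KO 2 months replicate 2 alone.

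**Figure D2:**
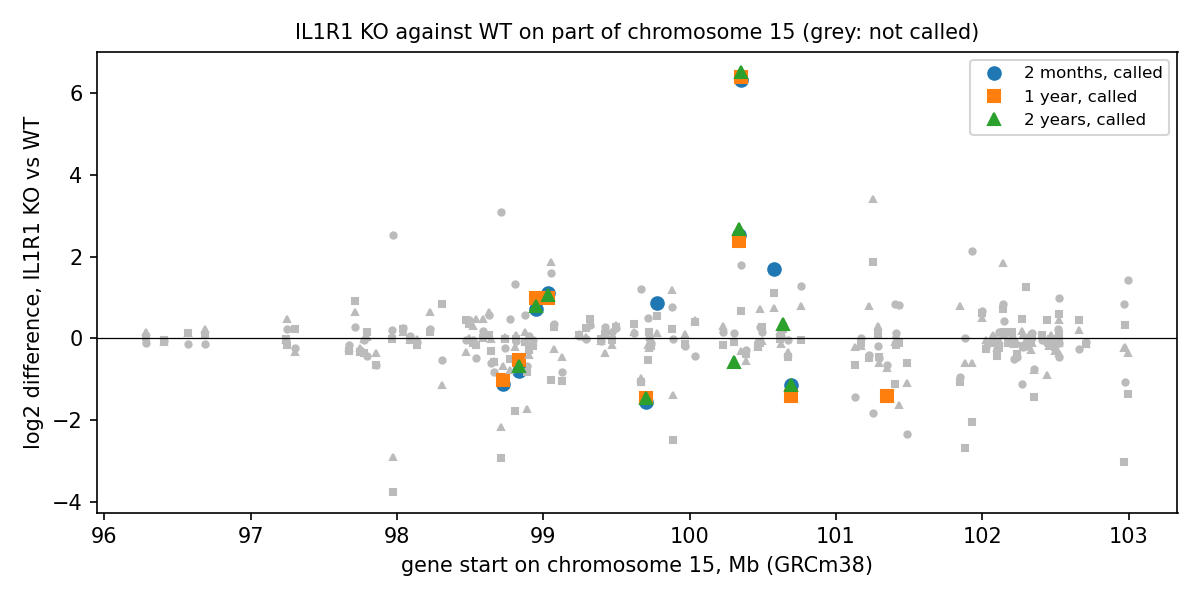
Limma log2 difference between libraries labelled IL1R1 KO and WT libraries (vertical axis) for tested genes by gene start on part of chromosome 15 in Mb, GRCm38 (horizontal axis), with 1 symbol per age and grey for genes that did not pass. Mettl7a2 lies at 6.32, 6.39 and 6.50 and Smarcd1 at -1.56, -1.44 and -1.46 at 2 months, 1 year and 2 years.

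At 1 year, the HSC ageing signature was lower in libraries labelled IL1R1 KO than in WT, at 11.0 ± 0.0678 (SD, n = 4) against 11.6 ± 0.0899 (SD, n = 5). Of 28 members, 10 were lower (21 adjusted over the list alone), with a median of -0.61 and adjusted p = 0.00154 with an estimated correlation. Examples were the integrin Itgb3 (-0.81 ± 0.13, SE, limma adjusted p = 5.39e-04), the caveolar protein Cavin2 (-0.68 ± 0.11, SE, adjusted p = 5.39e-04) and Sbspon (-1.54 ± 0.30, SE, adjusted p = 5.43e-03). Selp was lower by -0.61 ± 0.16 (SE, adjusted p = 0.0446), a call that ended in 12 of its 22 alternatives. Among these were the fits without WT 1 year replicates 3, 4 and 5 (adjusted p = 0.109, 0.0964 and 0.142) and without IL1R1 KO 1 year replicates 1, 2 and 4 (adjusted p = 0.0709, 0.210 and 0.108). Nfkbia, an inhibitor and target of NF-kB, was 5873 ± 437 (SD, n = 4) against 10217 ± 1030 (SD, n = 5). Its log2 difference of -0.80 ± 0.17 (SE, adjusted p = 0.0132) did not pass without IL1R1 KO 1 year replicate 2 (adjusted p = 0.0504). Heat shock genes were higher in 7 of 20 members (11 adjusted over the list alone; adjusted p = 0.0373 with an estimated correlation). From 2 months to 1 year their list went from 12.2 ± 0.158 (SD, n = 4) to 11.5 ± 0.227 (SD, n = 5) in WT, where 3 of 20 members fell (7 adjusted over the list alone; adjusted p = 0.323 with an estimated correlation). In libraries labelled IL1R1 KO it stood at 12.6 ± 0.186 (SD, n = 3) and 12.5 ± 0.222 (SD, n = 4), with 1 of 20 lower (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.956 with an estimated correlation). Higher than in WT at 1 year were Hspa1a (6.52 ± 0.84, SE), the chaperone Hspa5 (1.18 ± 0.18, SE) and Dnajb1 (1.80 ± 0.29, SE).

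Erythroid markers were also higher in libraries labelled IL1R1 KO at 1 year, at 9.35 ± 0.580 (SD, n = 4) against 7.64 ± 0.722 (SD, n = 5), with 4 of 13 members called (7 adjusted over the list alone; adjusted p = 0.225 with an estimated correlation). Among the largest rises outside that list were the red cell membrane genes Sptb (4.36 ± 0.79, SE), Kel (3.99 ± 0.91, SE) and Rhd (3.60 ± 0.70, SE). The call of Kel ended in 4 of the 9 fits with 1 library left out. Immediate early genes stood at 12.5 ± 0.597 (SD, n = 4) against 11.0 ± 1.01 (SD, n = 5), with 0 of 22 members called by limma, 14 adjusted over the list alone and 18 at an unadjusted p under 0.05 (adjusted p = 0.290 with an estimated correlation). In all, 221 genes passed, 113 higher and 108 lower. The count was 98, 141 and 140 without IL1R1 KO 1 year replicates 2, 1 and 3, 135 without WT 1 year replicate 5, 60 with the immediate early covariate and 51 with the erythroid covariate. It was 129 with the library of disagreeing age labels at 2 months, 141 with the replicate block, 340 without the 6 high-Mpo libraries, 474 with array quality weights and 356 with only the groups compared.

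At 2 years, the HSC ageing signature averaged 11.6 ± 0.108 (SD, n = 5) in libraries labelled IL1R1 KO and 11.5 ± 0.181 (SD, n = 4) in WT, and the list was not called. Immediate early genes stood at 12.8 ± 0.0794 (SD, n = 5) against 11.0 ± 1.05 (SD, n = 4). Of 22 members, 3 were higher (20 adjusted over the list alone; adjusted p = 0.250 with an estimated correlation), namely Klf2 (2.61 ± 0.62, SE), Klf6 (1.96 ± 0.50, SE) and Ier2 (1.21 ± 0.31, SE). These 3 calls ended in 7, 7 and 8 of the 9 fits with 1 library left out. Other rises were of Sik1, a salt-inducible kinase (3.19 ± 0.69, SE, limma adjusted p = 0.0188), the phosphatase Dusp5 (3.00 ± 0.66, SE, adjusted p = 0.0179) and Tiparp (2.39 ± 0.50, SE, adjusted p = 0.0124). None of these 3 passed without WT 2 years replicate 2 (adjusted p = 0.0910, 0.0951 and 0.0610), nor Sik1 without replicate 4 (adjusted p = 0.0797). Ly6a, the surface antigen Sca-1, was lower by -0.48 ± 0.11 (SE, adjusted p = 0.0199), a call that ended in 3 of those 9 fits. Erythroid markers averaged 10.3 ± 0.174 (SD, n = 5) against 8.96 ± 0.796 (SD, n = 4), with 0 of 13 called by limma, 1 adjusted over the list alone and 6 at an unadjusted p under 0.05 (adjusted p = 0.323 with an estimated correlation). Mast cell markers stood at 2.29 ± 0.777 (SD, n = 5) against 6.26 ± 1.52 (SD, n = 4), with 0 of 7 called by limma, 5 adjusted over the list alone and 5 at an unadjusted p under 0.05 (adjusted p = 0.363 with an estimated correlation). B cell markers averaged 6.12 ± 0.785 (SD, n = 5) against 7.32 ± 0.788 (SD, n = 4), with 0 of 15 called by limma, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (adjusted p = 0.643 with an estimated correlation). Monocyte markers averaged 5.66 ± 0.297 (SD, n = 5) against 6.75 ± 1.13 (SD, n = 4), with 0 of 13 called by limma, also adjusted over the list alone, and 0 at an unadjusted p under 0.05 (adjusted p = 0.660 with an estimated correlation). The monocyte difference of -1.08 was -1.63 without WT 2 years replicate 2. In all, 241 genes passed, 169 higher and 72 lower. The count was 129 and 124 without WT 2 years replicates 2 and 4, 143, 145 and 141 without IL1R1 KO 2 years replicates 3, 4 and 5, and 158 with the library of disagreeing age labels at 2 months. It was 41 with the immediate early covariate (22 higher and 19 lower), 133 with the erythroid covariate and 535 with array quality weights.

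**Figure D3:**
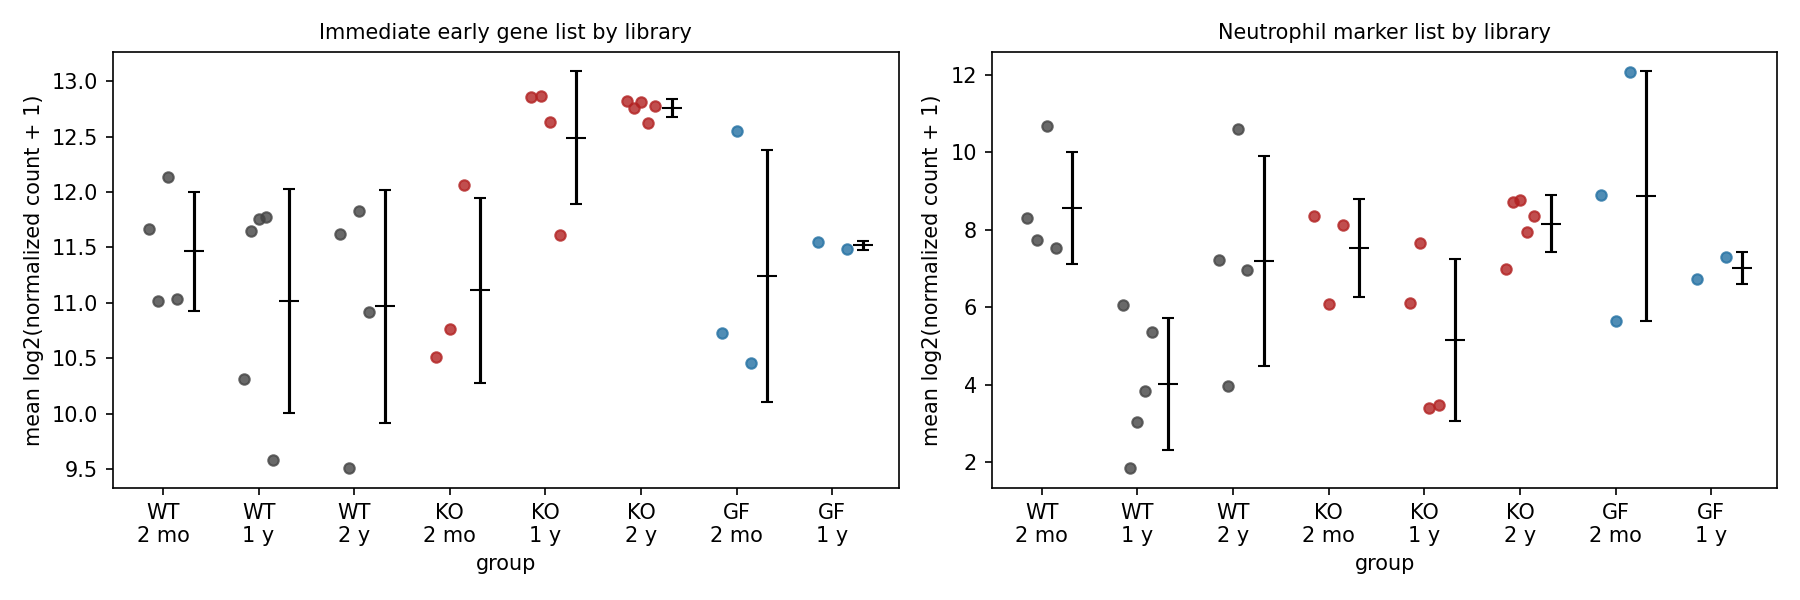
Mean log2(normalized count + 1) of the immediate early gene list (left) and the neutrophil marker list (right) in each library (points) by group (horizontal axis), with the group mean and SD. The 5 libraries labelled IL1R1 KO of 2 years average 12.8 for immediate early genes, and WT libraries average 8.56 at 2 months and 4.03 at 1 year for neutrophil markers.

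Whether the age change itself differed between libraries labelled IL1R1 KO and WT was tested as a difference of changes. At 1 year, the HSC ageing signature rose less in libraries labelled IL1R1 KO, with a mean difference of -0.71, a median of -0.57 and adjusted p = 0.0173 with an estimated correlation. By limma 0 of its 28 members were called over all genes, 10 adjusted over the list alone and 14 at an unadjusted p under 0.05. Selp differed by -0.34 ± 0.24 (SE, limma adjusted p = 0.670) and Nupr1 by -0.61 ± 0.26 (SE, adjusted p = 0.419). Over all genes 6 were called, 1 higher and 5 lower, including Rel (1.60 ± 0.28, SE, adjusted p = 0.0181), Clca3a1 (-1.32 ± 0.18, SE, adjusted p = 8.87e-04) and Rsrp1, a splicing-related gene (-0.90 ± 0.16, SE, adjusted p = 0.0181). Calls of Rel and Rsrp1 ended in 3 and 4 of the 16 fits with 1 library left out. Heat shock genes had a mean difference of 0.66, with 0 of 20 called by limma, 4 adjusted over the list alone and 5 at an unadjusted p under 0.05 (adjusted p = 0.361 with an estimated correlation). Endothelial and stromal markers had one of -1.32, with 0 of 9 called by limma, 2 adjusted over the list alone and 2 at an unadjusted p under 0.05 (adjusted p = 0.323 with an estimated correlation). Neutrophil markers had one of 2.17, with 0 of 13 called by limma, also adjusted over the list alone, and 1 at an unadjusted p under 0.05 (adjusted p = 0.660 with an estimated correlation). Without IL1R1 KO 2 months replicate 2 or IL1R1 KO 1 year replicate 2 it was 1.44 or 1.34. The count of 6 became 1 without WT 1 year replicate 3 or IL1R1 KO 1 year replicate 2, 3 without WT 2 months replicate 4, and 12, 15, 13 and 31 without WT 2 months replicate 2, IL1R1 KO 2 months replicates 1 and 3 and IL1R1 KO 1 year replicate 4. It was 1 with the immediate early covariate, 10 with array quality weights and 38 without the 6 high-Mpo libraries, where IL1R1 KO 2 months replicate 2 stood alone. Higher changes were the majority without IL1R1 KO 2 months replicate 3 (8 higher, 5 lower), without IL1R1 KO 1 year replicate 4 (20 and 11) and in that fit with 1 such library (32 and 6), and with array weights the numbers were equal (5 and 5).

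At 2 years, 67 genes had a different age change, 53 with a higher and 14 with a lower change in libraries labelled IL1R1 KO. The HSC ageing signature was not among the lists called. Higher changes were found for Cd28, a costimulatory receptor of T cells (7.44 ± 1.62, SE, limma adjusted p = 0.0395), the Notch target Hes1 (6.53 ± 1.43, SE, adjusted p = 0.0430) and Sik1 (5.01 ± 1.05, SE, adjusted p = 0.0335). Csrnp1 (3.31 ± 0.62, SE, adjusted p = 0.0221) and the clock gene Per1 (3.00 ± 0.57, SE, adjusted p = 0.0221) also had higher changes. Rsrp1 (-1.23 ± 0.16, SE, adjusted p = 3.22e-04) and the integrin Itga4 (-0.96 ± 0.19, SE, adjusted p = 0.0221) had lower changes. Calls of Cd28, Hes1 and Sik1 ended in 12, 13 and 11 of the 16 fits with 1 library left out, and those of Csrnp1, Per1 and Itga4 in 3, 2 and 2. Immediate early genes had a mean difference of 2.14, with 0 of 22 members called by limma over all genes, 10 adjusted over the list alone and 13 at an unadjusted p under 0.05 (adjusted p = 0.323 with an estimated correlation). Mitochondrial transcripts had one of -0.68, or -0.96 and -0.31 without IL1R1 KO 2 months replicates 2 and 3, with 0 of 13 called by limma, also adjusted over the list alone, and 8 at an unadjusted p under 0.05 (adjusted p = 0.412 with an estimated correlation). Neutrophil markers had one of 1.996, with 0 of 13 called by limma, also adjusted over the list alone, and 2 at an unadjusted p under 0.05 (adjusted p = 0.695 with an estimated correlation). It was 1.29 without WT 2 months replicate 3, 0.93 and 3.13 without WT 2 years replicates 2 and 3, and 1.27 without IL1R1 KO 2 months replicate 2. With the immediate early covariate 1 gene was left, with the B cell covariate 39, and with the library of disagreeing age labels at 2 months limma called 0 (1360 genes at an unadjusted p under 0.05). The count was 106 with array quality weights, 113 with only the groups compared and 112 without the 6 high-Mpo libraries, again with that replicate alone. Without WT 2 months replicates 1 and 3 it was 38 and 16, and without WT 2 years replicates 2, 3 and 4 it was 6, 109 and 19. Without IL1R1 KO 2 months replicates 1 and 2 it was 7 and 35, and without IL1R1 KO 2 years replicates 1 to 5 it was 34, 34, 30, 32 and 22.

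Genes that changed with age in the mean of both genotypes numbered 1995 at 1 year and 2192 at 2 years. At 1 year their change was smaller in libraries labelled IL1R1 KO for 66.8% of genes, with a median difference of -0.17 on the log2 scale and median changes of 0.70 in WT and 0.55 in libraries labelled IL1R1 KO. At 2 years it was smaller for 43.8%, with a median difference of 0.05. Of 100 arrangements with genotype permuted within age, 13 gave a median as far from 0 at 1 year and 48 at 2 years, so neither median passed this permutation test. The 1-year median was -0.238 without WT 2 months replicate 1, and -0.0776 and -0.0775 without IL1R1 KO 2 months replicates 2 and 3. The 2-year median was -0.00846 without WT 2 years replicate 1 and 0.124 and 0.125 without IL1R1 KO 2 months replicates 2 and 3.

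At 2 months, germ-free libraries differed from WT in genes of the HSC ageing signature. Selp was 927 ± 198 (SD, n = 3) against 2314 ± 642 (SD, n = 4), a log2 difference of -1.30 ± 0.18 (SE, limma adjusted p = 7.00e-05). Clu was lower by -1.32 ± 0.24 (SE, adjusted p = 0.00282) and Nupr1 by -1.03 ± 0.20 (SE, adjusted p = 0.00637). Of the 28 members, 5 were lower and 1 higher (13 and 2 adjusted over the list alone; adjusted p = 0.260 with an estimated correlation), the higher one being Itgb3 (0.75 ± 0.15, SE). Cxcr4, the receptor that holds HSCs in the marrow, was higher by 2.28 ± 0.34 (SE, adjusted p = 2.12e-04) and Zbtb16, a transcription factor, by 2.24 ± 0.43 (SE, adjusted p = 0.00614). Dhcr7, an enzyme of cholesterol synthesis, was lower by -1.68 ± 0.23 (SE, adjusted p = 7.00e-05), Rbpjl by -5.02 ± 0.58 (SE, adjusted p = 5.09e-06), and the histone gene Hist1h4m by -6.23 ± 0.53 (SE, adjusted p = 2.99e-08). Nupr1 and Zbtb16 did not pass without germ-free 2 months replicate 2 (adjusted p = 0.109 and 0.0706), nor Itgb3 without replicate 3 (adjusted p = 0.0969). Erythroid markers stood at 10.1 ± 0.457 (SD, n = 3) against 9.08 ± 0.763 (SD, n = 4), with 0 of 13 called by limma, also adjusted over the list alone, and 5 at an unadjusted p under 0.05 (adjusted p = 0.604 with an estimated correlation). Lymphoid priming genes stood at 7.96 ± 1.34 (SD, n = 3) against 7.08 ± 0.433 (SD, n = 4), with 0 of 18 called by limma, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (adjusted p = 0.412 with an estimated correlation). Their mean difference of 0.88 was 0.55, 1.65 and 0.44 without germ-free 2 months replicates 1 to 3. B cell markers stood at 6.38 ± 2.31 (SD, n = 3) against 5.58 ± 1.04 (SD, n = 4), with 1 of 15 higher (3 adjusted over the list alone; adjusted p = 0.574 with an estimated correlation). Their mean difference of 0.81 was 0.31, 2.13 and -0.0133 in the same fits and 0.46 without WT 2 months replicate 1. Without the 6 high-Mpo libraries, where germ-free 2 months replicate 2 stood alone, the 2 list means were -0.44 and -0.94. Heat shock genes stood at 11.7 ± 0.122 (SD, n = 3) against 12.2 ± 0.158 (SD, n = 4), with 0 of 20 called by limma, also adjusted over the list alone, and 3 at an unadjusted p under 0.05 (adjusted p = 0.502 with an estimated correlation). In all, 102 genes passed, 51 higher and 51 lower. The count was 67 without germ-free 2 months replicate 3, 37 with only the groups compared (25 higher and 12 lower), 56 with array quality weights, 61 with the erythroid covariate and 173 in that fit with 1 germ-free library, where 29 were higher and 144 lower.

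At 1 year, Selp was lower in germ-free libraries than in WT by -1.11 ± 0.20 (SE, limma adjusted p = 0.00155), Nupr1 by -0.99 ± 0.22 (SE, adjusted p = 0.00842) and Ehd3 by -1.20 ± 0.18 (SE, adjusted p = 2.22e-04). Of the HSC ageing signature, 8 of 28 members were lower (11 adjusted over the list alone; adjusted p = 0.241 with an estimated correlation). Flt3, a receptor of lymphoid-primed progenitors, was 1525 ± 78.1 (SD, n = 2) against 397 ± 165 (SD, n = 5), higher by 2.02 ± 0.42 (SE, adjusted p = 0.00640). Mki67 was higher by 0.94 ± 0.19 (SE, adjusted p = 0.00587), while 4 of 36 cell cycle members were higher and 1 lower (also 4 and 1 adjusted over the list alone; adjusted p = 0.747 with an estimated correlation). Cytosolic ribosomal protein genes were higher in 4 of 73 members (35 adjusted over the list alone; adjusted p = 0.491 with an estimated correlation). Without germ-free 1 year replicates 1 and 2, the cell cycle mean of 0.21 was 0.42 and 0.00151, and the ribosomal mean of 0.29 was 0.09 and 0.49. Erythroid markers stood at 10.1 ± 0.838 (SD, n = 2) against 7.64 ± 0.722 (SD, n = 5), with 5 of 13 members higher (9 adjusted over the list alone; adjusted p = 0.254 with an estimated correlation). Outside that list, Kel (5.16 ± 1.14, SE) and Rhd (4.75 ± 0.87, SE) were also higher. Without germ-free 1 year replicate 1, Selp, Flt3, Mki67 and Kel did not pass (adjusted p = 0.0548, 0.0918, 0.0625 and 0.107), nor Nupr1 without replicate 2 (adjusted p = 0.199). The neutrophil list averaged 7.01 ± 0.412 (SD, n = 2) against 4.03 ± 1.70 (SD, n = 5). Limma called 0 of 13 members, also adjusted over the list alone, and 5 at an unadjusted p under 0.05 (adjusted p = 0.574 with an estimated correlation). Heat shock genes stood at 11.1 ± 0.0252 (SD, n = 2) against 11.5 ± 0.227 (SD, n = 5), with 1 of 20 lower (4 adjusted over the list alone; adjusted p = 0.518 with an estimated correlation). In all, 841 genes passed, 310 higher and 531 lower. The count was 150 without germ-free 1 year replicate 1, 540, 477, 469 and 514 without WT 1 year replicates 2 to 5, 418 with the replicate block, 462 with array quality weights and 31 with the erythroid covariate.

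The age change to 1 year of germ-free libraries was set against that of WT. By limma, 0 genes differed, with 1794 at an unadjusted p under 0.05. Selp differed by 0.19 ± 0.27 (SE, adjusted p = 0.850), Nupr1 by 0.03 ± 0.29 (SE, adjusted p = 0.979) and Flt3 by 1.63 ± 0.57 (SE, adjusted p = 0.303), and the HSC ageing signature was not called. Mitochondrial transcripts had a mean difference of 0.68, with 0 of 13 members called by limma, 1 adjusted over the list alone and 4 at an unadjusted p under 0.05 (adjusted p = 0.491 with an estimated correlation). Neutrophil markers had one of 2.68, or 1.06 and 4.28 without germ-free 2 months replicates 2 and 3, with 0 of 13 called by limma, also adjusted over the list alone, and 0 at an unadjusted p under 0.05 (adjusted p = 0.643 with an estimated correlation). Erythroid markers had one of 1.36, or 0.77 without germ-free 1 year replicate 2, with 0 of 13 called by limma, 3 adjusted over the list alone and 4 at an unadjusted p under 0.05 (adjusted p = 0.446 with an estimated correlation). Immediate early genes had one of 0.72, with 0 of 22 called by limma, also adjusted over the list alone, and 4 at an unadjusted p under 0.05 (adjusted p = 0.732 with an estimated correlation). It was 0.37 without WT 1 year replicate 5, 0.46, 1.38 and 0.33 without germ-free 2 months replicates 1 to 3, and -0.14 without the 6 high-Mpo libraries. Ribosomal protein genes had one of 0.30, or 0.11 and 0.50 without germ-free 1 year replicates 1 and 2, with 0 of 73 called by limma, 1 adjusted over the list alone and 22 at an unadjusted p under 0.05 (adjusted p = 0.491 with an estimated correlation). Cell cycle, oxidative phosphorylation and both interferon lists had means between -0.25 and 0.23, with adjusted p of 0.586 or more with an estimated correlation. The count was 7, 2, 7, 4, 1, 1 and 59 without WT 2 months replicates 2 and 3, WT 1 year replicate 1, germ-free 2 months replicates 1 and 2, and germ-free 1 year replicates 1 and 2. It was 13 with no filter on low values and 101 without the 6 high-Mpo libraries, with 1 germ-free library left at 2 months in that fit.

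Genes that differed from WT in both libraries labelled IL1R1 KO and germ-free libraries numbered 10 at 2 months, 8 higher and 2 lower in both, with 1 called in opposite directions. At 1 year they numbered 65, 34 higher and 31 lower in both, with 3 in opposite directions. Kel, Rhd, Sptb, Cldn13 and Ermap were among the largest rises of both comparisons at 1 year, and Ermap is 1 of the erythroid markers. Against WT, the call of Cldn13 ended in 6 of 9 fits with 1 library left out for IL1R1 KO and in 2 of 7 for germ-free, those of Ermap in 1 and 2, Kel in 4 and 1, Sptb in 0 and 1, and Rhd in 0 and 0. Both comparisons use the same WT libraries. Independent lists would share 0.123 higher and 0.0842 lower genes at 2 months and 2.07 and 3.38 at 1 year. In 100 simulations of unchanged groups against these WT libraries, 0 were shared at both ages. Unchanged groups leave few genes to call. That 0 therefore cannot show how many shared genes the common WT libraries add when both groups do differ. With the WT libraries split between the comparisons, 4 to 7 genes were shared at 2 months (6 splits, mean 4.83) and 3 to 16 at 1 year (20 splits, mean 10.1). Across genes, which are not independent replicates, fold changes correlated with r = 0.364 at 2 months (simulated mean 0.425, split mean -0.0320) and 0.397 at 1 year (simulated mean 0.348, split mean 0.194). Their covariance was 0.187 and 0.210, against simulated values of 0.169 and 0.135, differences of 0.0181 and 0.0748, and split means of -0.0253 and 0.120. The shared count at 2 months was 6 without IL1R1 KO 2 months replicate 1 or 3, without germ-free 2 months replicate 3, with array quality weights or without the 6 high-Mpo libraries (1 library left in each of these 2 groups), and 4 with only the groups compared. At 1 year it was 39, 35, 39 and 31 without WT 1 year replicates 2 to 5, 38, 26 and 38 without IL1R1 KO 1 year replicates 1 to 3, and 24 and 40 without germ-free 1 year replicates 1 and 2. It was 32 with the replicate block, 33 with the library of disagreeing age labels at 2 months, 18 with the immediate early covariate and 5 with the erythroid covariate.

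Over all 13 comparisons, 128 of the 312 list tests passed with the preset correlation and 8 with an estimated one. Of the 8, 7 were of the HSC ageing signature and 1 of the heat shock list. Lists with no call in any comparison were IL-1 signalling (smallest camera adjusted p = 0.0897), p53 and senescence (0.0555), T and NK cell markers (0.181) and sex-linked transcripts (0.0634). Single members did pass, such as Cdkn2c, a cyclin-dependent kinase inhibitor, which rose in WT by 1.20 ± 0.26 (SE, limma adjusted p = 0.00233) at 1 year and by 1.35 ± 0.27 (SE, adjusted p = 0.00199) at 2 years. Il1rl1, the interleukin-33 receptor, was higher in libraries labelled IL1R1 KO by 3.09 ± 0.69 (SE, adjusted p = 0.0162) and in germ-free libraries by 4.24 ± 0.86 (SE, adjusted p = 0.00548) at 1 year. These calls of Il1rl1 ended in 4 of 9 fits with 1 library left out and, for germ-free, without germ-free 1 year replicate 2 (adjusted p = 0.138). Klrb1c, the NK1.1 antigen, rose at 1 year in WT by 2.18 ± 0.21 (SE, adjusted p = 1.64e-08). Endothelial and stromal markers passed in 2 comparisons, HSC identity in 6, lymphoid priming in 3, myeloid priming in 3, monocyte markers in 5 and mast cell markers in 4, all with adjusted p of 0.0853 or more with an estimated correlation.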

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

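Tests of chromosome segments, of genes with similar names, of the Il1r1 locus, of the 6 high-Mpo libraries, of cell handling, of depth and of splits with the germ-free libraries of 1 year were chosen after the results they measure had been seen, and so were the fits with a list as covariate.

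Of 100 checks of single libraries against the rest of their group, 7 stood apart, and chance gives about 1 in 20. Selp was 3275 in WT 2 months replicate 4, against 1968 to 2038 in the other libraries of the group. Nupr1 was 5389 in IL1R1 KO 1 year replicate 2, against 4504 to 4543. Vwf was 4843 in the same library, against 7139 to 7585. Flt3 was 685 in WT 1 year replicate 1, against 284 to 384. Flt3 was 1207 in WT 2 years replicate 1, against 266 to 391. Estimated depth was 19.3 M reads in IL1R1 KO 2 years replicate 1, against 30.9 to 35.3 M. The erythroid list stood at 7.77 in WT 2 years replicate 2, against 9.25 to 9.46.

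The age change differed between libraries labelled IL1R1 KO and WT in 6 genes at 1 year and 67 at 2 years, by a test of the difference itself. The HSC ageing signature differed by -0.71 at 1 year. Single genes at 1 year were Rel (1.60), Clca3a1 (-1.32), Slc24a5 (-1.10) and Rsrp1 (-0.90). At 2 years they were Cd28 (7.44), Hes1 (6.53), Sik1 (5.01), Skil (3.69), Tiparp (3.38), Csrnp1 (3.31), Plaur (3.26), Per1 (3.00), Slc35g2 (-3.15), Cdk5rap1 (-1.99), Rsrp1 (-1.23), Paxbp1 (-1.21), Mms19 (-1.13), Itga4 (-0.96), Lpar6 (-0.88) and Hsd17b4 (-0.86). Of the 29 alternatives of each, Clca3a1 passed in 29, Rsrp1 at 2 years in 28, Sik1 in 15, Cd28 and Tiparp in 13, Hes1 and Hsd17b4 in 11, Lpar6 in 10 and Slc35g2 in 8, and the others in 20 to 25.

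Other splits of the same libraries bear on each count of genes. For WT at 1 year, 1 of 100 splits, the real one, called as many as 1818 genes, and the highest other called 941. For WT at 2 years it was 1 of 35 (941 genes, highest other 22). For libraries labelled IL1R1 KO it was 1 of 35 at 1 year (340, highest other 61) and 1 of 56 at 2 years (1360, highest other 12). Against WT they gave 1 of 35 at 2 months (69, highest other 50), 1 of 100 at 1 year (221, highest other 85) and 1 of 100 at 2 years (241, highest other 16). The differences of age changes gave 2 of 100 at 1 year (6, highest other 7) and 2 of 100 at 2 years (67, highest other 115). A chance split of libraries can be excluded for these at a share of 0.05. For germ-free against WT at 2 months, 2 of 35 splits called as many as 102 genes and chance cannot be excluded. The highest other split called 232 and set the 4 libraries with high Mpo of these groups against the rest, which points to a structure of the samples other than their group. With 2 germ-free libraries of 1 year, only the real split of 21 against WT reached 841 genes (highest other 25). That smallest possible share just passes. Against the germ-free libraries of 2 months, 10 splits are too few for a share under 0.05 (1 of 10; 356 genes, highest other 140). The germ-free difference of age changes called 0 genes, which each of 100 arrangements reaches (highest other 40), so this says nothing about chance.

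The number of lists called per comparison was mostly reached by other splits. For WT it was 16 at 1 year (4 of 100 splits, highest other 16), a share under 0.05, and 13 at 2 years (2 of 35, highest other 14), where chance cannot be excluded. It also cannot for libraries labelled IL1R1 KO with 10 lists at 1 year (11 of 35, highest other 14) and 13 at 2 years (4 of 56, highest other 13). The same holds against WT with 9 at 2 months (14 of 35, highest other 14), 9 at 1 year (34 of 100, highest other 13) and 3 at 2 years (95 of 100, highest other 9), for germ-free libraries with 7 at 2 months (20 of 35, highest other 15), and for the differences of age changes with 12 at 1 year (7 of 100, highest other 14) and 6 at 2 years (56 of 100, highest other 14). Nor can it for germ-free libraries at 1 year with 8 lists against WT (9 of 21, highest other 11) and 9 in the difference of age changes (30 of 100, highest other 17), while for their 14 lists with age 10 splits are too few (2 of 10, highest other 16). The HSC ageing signature, lower by -0.63 in libraries labelled IL1R1 KO at 1 year, was as far from 0 in 1 of 100 splits, the real one, with 0.540 as the highest other, so chance can be excluded for it. For the shared ageing genes, 13 of 100 permutations reached the 1-year median of -0.170 (highest other 0.237) and 48 of 100 the 2-year median of 0.0524 (highest other 0.218), so chance cannot be excluded.

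Of the 27 genes that differed between libraries labelled IL1R1 KO and WT at all 3 ages, 20 lay within 5 Mb of another one, in stretches of chromosomes 1, 4, 8, 14, 15 and 17, against a median of 4 and a maximum of 14 in 10000 random draws (permutation p = 0.0001, the smallest they can give). A segment around Il1r1 alone is argued against, since 24 of the 27 lie on other chromosomes. Segments that differ in strain between the WT and knockout colonies are consistent with the clustering and may account for part of these genes. Reads shared between similar genes stay open, since 7 of the 27 have a neighbour within 1 Mb with the same name stem, between the bounds set for that test. An effect of the receptor itself on these genes was not tested and stays open.

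Libraries of 2 months carried neutrophil and myeloid transcripts unevenly, and 6 of them had Mpo of at least 20000. The neutrophil fall in WT at 1 year had a list mean of -5.46 without them and -4.53 with all libraries. Of 13 members 7 were called (adjusted p = 0.323 with an estimated correlation). Of the 6, only WT 2 months replicates 2 and 4 enter this comparison. They already had the lowest levels of their group (7.73 and 7.52), so leaving them out could only enlarge the fall and tests nothing. The 6 are argued against as the source of the rise of the HSC ageing signature, which was 1.99 without them and 1.98 with all. Other cells in the sort could still supply the neutrophil transcripts, and a change of HSC priming with age stays open.

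Immediate early genes had a mean difference of 1.79 between libraries labelled IL1R1 KO and WT at 2 years. With an estimated correlation, adjusted p was 0.250. The 3 of 22 calls ended in 7 or 8 of 9 fits with 1 library left out. Depth is argued against. In WT the list fell with depth, from 11.8 at 23.6 M reads to 9.51 at 29.6 M. IL1R1 KO libraries, 1 at 19.3 M and others at 30.9 to 35.3 M, ranged over 0.200. Handling of cells before lysis and the genotype cannot be told apart, since the list ranged over 2.32 within the WT libraries alone and sort days are not given in the sources used here. The handling test also asked for a higher heat shock list, and this was not met. Its mean was 0.09 (-0.0479 to 0.185 over alternatives), with 4 of 20 higher (adjusted p = 0.614 with an estimated correlation). This does not exclude handling. A first form asked whether any of the 4 WT libraries reached the lowest IL1R1 KO one, and 0 did. Its bound counted this against handling. It was replaced once this was seen, as handling differing between whole groups also gives 0. At 1 year, not tested for handling, both lists were higher in IL1R1 KO (12.5 against 11.0 and 12.5 against 11.5).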

How the results depend on the processing

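Fits without the 6 high-Mpo libraries and with a list as covariate were chosen after the values had been seen; all others were set before the data were examined. The HSC ageing signature kept its sign and passed in all its alternatives at the preset correlation, with means of -0.708 to -0.598 for IL1R1 KO against WT at 1 year (adjusted p up to 5.64e-15), -1.05 to -0.557 for the difference of age changes at 1 year (adjusted p up to 5.44e-09) and 1.95 to 2.04 in WT at 1 year. Of settings fixed beforehand other than single left-out libraries, 130 counts and medians stayed within 1.5 times or the replicate spread, 29 moved and 1 reversed. Of list results there, 979 stayed called and 45 were lost, and of named genes 3253 and 535. With single libraries left out, 154 counts and medians stayed, 71 moved and 1 reversed. Of list results 1019 stayed called, 154 were lost and 3 reversed, and of named genes 3002 stayed called and 891 were lost. The pseudocount of 5, the filter on a mean of 50 and quantile normalization moved no count past 1.5 times. No count test was run without whole reads. The cause of a change was not tested, except that a fit with fewer libraries has less power. Depth (at least 15.6 M reads) limits low genes.

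Settings fixed beforehand gave these values. With no filter, 13 genes differed in age change between germ-free and WT. With the replicate block, IL1R1 KO against WT at 1 year gave 141, germ-free against WT at 1 year 418 and their overlap 32; the block moved no other count past 1.5 times. Replicate numbers did not pair libraries, as deviations of same-numbered libraries correlated at 0.00941 on average over 88 pairs (-0.110 to 0.165), against -0.00273 over 302 other pairs. With array quality weights, the germ-free age change gave 133, IL1R1 KO against WT 40, 474 and 535 by age, germ-free against WT 56 and 462, the difference of age changes for IL1R1 KO 10 and 106, and the overlap at 2 months 6. With the library of disagreeing age labels at 2 months, the IL1R1 KO age changes gave 58 and 710, IL1R1 KO against WT 129 at 1 year and 158 at 2 years, and the difference of age changes at 2 years 0 by limma (1360 at an unadjusted p under 0.05). The shared ageing medians were -0.247 at 1 year and -0.0840 at 2 years, the latter reversed, and the overlap at 1 year was 33. With only the groups compared, WT at 2 years gave 342, IL1R1 KO at 1 year 50, germ-free at 1 year 10, IL1R1 KO against WT 19 at 2 months and 356 at 1 year, germ-free against WT at 2 months 37, the difference of age changes at 2 years 113 and the overlap at 2 months 4.

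Added settings gave these. Without the 6 high-Mpo libraries, which leaves 1 IL1R1 KO and 1 germ-free library at 2 months, WT at 1 year gave 988, IL1R1 KO 162 and 461, IL1R1 KO against WT at 1 year 340, germ-free against WT at 2 months 173, the differences of age changes 38, 112 and, for germ-free, 101, and the overlap at 2 months 6. List means reversed there for erythroid markers in IL1R1 KO at 1 year (0.784), in germ-free at 1 year for myeloid priming (1.74), neutrophil (1.38), monocyte (0.426) and mast cell markers (1.80), in germ-free against WT at 2 months for lymphoid priming (-0.439) and B cell markers (-0.937), and for immediate early genes in the germ-free difference of age changes (-0.144). With the myeloid covariate, WT at 1 year gave 982 and its mast cell list 0.616. With the B cell covariate, the difference of age changes at 2 years gave 39. With the immediate early covariate, IL1R1 KO gave 166 and 709, IL1R1 KO against WT 60 at 1 year and 41 at 2 years, the differences of age changes 1 and 1, the overlap at 1 year 18, and the ribosomal list in the 2-year difference 0.00802. With the erythroid covariate, WT at 1 year gave 868, IL1R1 KO against WT 51 and 133, germ-free against WT 61 and 31, the overlap at 1 year 5, and the mitochondrial list 0.0645 in WT at 1 year and -0.312 in germ-free against WT at 1 year.

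With each library left out in turn, counts ranged over 1278 to 1687 (WT at 1 year), 680 to 926 (WT at 2 years), 94 to 372 and 753 to 1174 (IL1R1 KO), 193 to 354 (germ-free), 39 to 69, 98 to 239 and 124 to 256 (IL1R1 KO against WT), 67 to 109 and 150 to 1221 (germ-free against WT), 1 to 31, 6 to 109 and, for germ-free, 0 to 59, where fits with 0 had 1565 to 1757 at an unadjusted p under 0.05 (differences of age changes), 114 to 150 (lists), and 6 to 12 and 24 to 97 (overlap). Medians of shared ageing genes ranged from -0.238 to -0.0775 at 1 year and from -0.00846, without WT 2 years replicate 1, to 0.125 at 2 years. List means reversed for mitochondrial transcripts in the 1-year difference without IL1R1 KO 2 months replicate 3 (0.0755, against -0.574 without replicate 2), and for oxidative phosphorylation in germ-free against WT at 1 year without germ-free 1 year replicate 1 (-0.0280, against 0.303 without replicate 2) and in germ-free at 1 year without replicate 2 (0.0594, against -0.271 without replicate 1). A library left alone in its group, at 2 months or 1 year, was assumed to vary like the other groups.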

Other observations

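The lists of further genes below were chosen after the leading genes had been seen and leave those genes out, while the tests on them were set before their values were seen.

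Some sterol synthesis genes were lower in germ-free libraries than in WT, while over 18 further genes of the pathway the test passed at 2 months and not at 1 year (adjusted p = 0.0427 and 0.0560). Dhcr7, which makes cholesterol in the last step of a branch of the pathway, was lower by -1.68 (limma adjusted p = 7.00e-05) at 2 months and -1.61 (adjusted p = 3.99e-04) at 1 year. Sqle, the squalene epoxidase, was lower by -0.80 (adjusted p = 0.0120) and -0.63 (adjusted p = 0.0376). Hmgcs1, the enzyme before the rate-limiting step, stood at -0.46 (adjusted p = 0.505) and -0.88 (adjusted p = 0.0331). Over the 18 further genes, Hmgcs1 among them, the mean difference was -0.39 at 2 months and -0.44 at 1 year, with 1 and 3 members called lower by limma. Camera with an estimated correlation gave p = 0.0107 and 0.0280, or 0.0427 and 0.0560 adjusted over the 4 such tests. The hypothesis that the pathway as a whole is lower in germ-free HSCs is consistent with these values, and the 1-year value of -0.44 misses the threshold once adjusted. Housing, diet and colony were not separated from germ-free status and stay open.

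Genes known to be induced by glucocorticoids were among those higher in germ-free libraries at both ages. Fkbp5, a co-chaperone of the glucocorticoid receptor, was higher by 1.02 (limma adjusted p = 0.0138) at 2 months and 1.34 (adjusted p = 0.00131) at 1 year, and Tsc22d3, the glucocorticoid-induced leucine zipper, by 1.31 (adjusted p = 0.00114) and 1.17 (adjusted p = 0.00605). Cxcr4 was higher by 2.28 (adjusted p = 2.12e-04) and 1.86 (adjusted p = 0.00513). Zbtb16 stood at 2.24 (adjusted p = 0.00614) and 0.93 (adjusted p = 0.265). Over 12 further such genes the mean was 0.37 at 2 months (camera with an estimated correlation p = 0.114, or 0.152 adjusted) and 0.0260 at 1 year (p = 0.724, also when adjusted). Of these 12, limma called 0 higher at either age, 0 lower at 2 months and 1 lower at 1 year, with 4 and 5 at an unadjusted p under 0.05 at the 2 ages, so a wider response was not shown and not excluded.

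In the germ-free comparison, 51 genes were called at both ages with 1 sign, 30 higher and 21 lower. Of these, 24 lay within 5 Mb of another one, against a median of 12 in random draws (permutation p = 0.0041). The set shares 5 genes with the 27 of the libraries labelled IL1R1 KO, namely Entpd4, Gm16867, Dynlt1b, Tmem181b-ps and Serinc3, each with the same sign in both. Both sets were drawn against the same WT libraries. Names in this paragraph were chosen after their values were seen.

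The library with disagreeing age labels, IL1R1 KO 1 year replicate 1, had an HSC ageing signature level of 11.0. The other 3 libraries of its group stood at 10.9, 11.0 and 10.9, and the 3 libraries labelled IL1R1 KO of 2 months at 9.71 ± 0.261 (SD, n = 3). Its group was taken from its title.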
